A study of Danio rerio with 4 samples.

How the data were processed

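Total RNA was taken from whole zebrafish embryos at 5 days post fertilization, wild type or homozygous for a sas10 mutant allele. Per the labels' protocols, an adapter was ligated to the 3′ ends, cDNA was made from the adapter, and libraries were amplified with a forward primer in the 5′ETS. The protocol states 3 independent repeats per genotype, and 2 libraries per genotype were analysed here. The series design also names a tbl3 mutant and human cells with reduced UTP3, which were not analysed here.

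The deposited files hold 1 line per read and no table of counts. Per the file headers, each line gives the position of the last encoded base, the encoded sequence, the untemplated sequence that follows it and the size of that addition in nt. The submitters' processing notes name the genome build GRCz11. The aligner, the adapter trimming, any removal of duplicates, and the rule that separated encoded from added bases are not given in the sources used here. Encoded sequences were 19 to 130 nt long and no read exceeded 130 nt with its tail, so RNAs shorter than 19 nt are missing and reads of RNAs ending beyond position 130 do not contain position 1. Reads that started at position 1 made up 92.8% and 92.7% of the wild-type libraries and 80.9% and 85.3% of the mutant libraries. The recorded size of the addition equalled the length of its sequence in 100.0% of lines.

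From these deposited positions, reads were tallied per 3′ end and library, which gave the counts used below. The sequence of the amplified region was rebuilt as the most frequent base at each position, and the start of 18S was found by its first 20 bases. Shares were computed as percent of a library's reads, for regions of 100 nt fixed before the data were examined (the last, 401 to 446, is shorter) and for 18S. Narrower windows were chosen after the data were examined. A tail is any recorded untemplated sequence of at least 1 nt. Intervals are 95% Wilson intervals. The files carry no molecular identifiers, and 97.7%, 97.8%, 95.4% and 95.4% of the lines of the libraries repeated an earlier line, so intervals cover counting error only. The measurements are relative shares, and no absolute amount of any RNA was available.

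A negative-binomial quasi-likelihood test on the counts of reads per 3′ end position and per region had been planned. It was not run, and limma (version 3.58.1, R 4.3.3) was applied to the tallied counts with voom weights in its place. Scaling used the trimmed mean of M values (TMM), computed with 30% of log ratios and 5% of mean levels trimmed at each end. The offset was 0.5 counts. Positions were tested where at least 2 libraries reached the equivalent of 10 reads in the median library and the total was at least 15. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Log2 changes with TMM are relative to the typical position, while regions were tested on library totals. The TMM factors were 0.601 and 0.671 for wild type and 1.53 and 1.62 for the mutant. The model held genotype alone. The fit of positions had 2 residual degrees of freedom and drew on 32.6 prior degrees of freedom pooled over positions. Its small p-values therefore rest mainly on that pooled variance and not on the 2 replicates of each genotype. Shares, tail measures and medians were compared by an exact two-sided permutation test over the 6 ways to split 4 libraries into 2 and 2, which cannot go below p = 0.33.

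On simulated data for this comparison, with 604 positions tested, 200 of them changed and a dispersion of 0.05, the test recovered 61.2% of 2-fold and 98.0% of 4-fold changes, and 4.27% of calls were false. The dispersion was a fixed setting not matched to the spread between the real replicates, and as many simulated positions rose as fell. These rates may therefore not hold for the real libraries. Replicates were compared before averaging. The chi-square per degree of freedom was 87.7 between the wild-type libraries and 222.2 between the mutant libraries. It takes reads as independent and cannot tell a second amplification of 1 RNA sample from a second group of embryos. Each library was counted as a separate sample because the labels list it as one. The median absolute log2 difference of a position's share between replicates was 0.541 in wild type and 0.752 in the mutant. No sequencing batch or date was given in the labels used here, so no value within a batch could be computed.

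The named positions were taken by a rule fixed before the data were examined. They are the 10 positions with the highest mean share in each genotype, and, among positions past the threshold whose TMM-scaled values did not overlap between genotypes, the 10 with the highest mean share that were higher and the 10 that were lower. This gave 24 positions. Positions 349, 442 and 616 are named outside that rule, after their values were seen: 349 is the wild-type peak of the ends at 301 to 446, 442 the mutant peak of the last 10 bases of the 5′ETS, and 616 the most abundant position past the threshold and higher that the rule leaves out. The alternatives were other scalings, filters and bin widths, limma-trend, a replicate block, each library left out, thinning to 1274810 reads, reads without mismatches (88.5%, 89.1%, 86.3% and 86.9% of reads), distinct combinations of end and tail counted once, reads of the main cluster at 51 to 58 left out of the regions and the median, and other definitions of a tail. A mismatch was a base carried by under 5% of the reads at its position, over all libraries together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and base pairing was predicted with RNAfold 2.7.2.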

Results

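Sas10, known as UTP3 in human cells, is a protein of the small-subunit processome, the nucleolar particle that assembles on the 5′ external transcribed spacer (5′ETS) of the ribosomal RNA precursor and in which the spacer is cut away from 18S rRNA. The 3′ ends of RNAs that hold the 5′ETS were sequenced from whole zebrafish embryos at 5 days post fertilization, in 2 wild-type libraries and 2 libraries of embryos homozygous for a sas10 mutant allele. The question was whether processing of the precursor is altered when Sas10 is lost. In 3′RACE sequencing an adapter is ligated to the 3′ ends of total RNA, and amplification from a primer in the 5′ETS then gives reads that end where the RNA ended, with several reads possible from 1 RNA after PCR. The sas10 transcript is not part of the amplified region, so these libraries hold no measurement of the mutated gene. The wild-type libraries held 3252812 and 3750607 reads, and the mutant libraries held 1899822 and 1274810.

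Positions are counted from 1 at the first base of most reads, whose sequence begins GACCGATGGGAACTTACGAC. On this scale 18S rRNA begins at position 447 with TACCTGGTTGATCCTGCCAG, and the 5′ETS runs to position 446. These are positions on the amplified RNA and not chromosome coordinates, since no genome sequence was used here.

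RNAs that hold the 5′ETS reached further towards 18S in the sas10 mutant. The median 3′ end was at position 55 in both wild-type libraries, and at 74 and 70 in the mutant libraries, a mean of 72.0 ± 2.83 (SD, n = 2). The 90th percentile lay at position 96 in both wild-type libraries and at 154 ± 19.8 (SD, n = 2) in the mutant. In wild type 91.2% ± 0.0433 (SD, n = 2) of reads ended within positions 1 to 100, against 79.0% ± 4.30 in the mutant. Among reads outside positions 51 to 58, which hold the main cluster of ends, the median was 73.0 in wild type and 84.0 in the mutant.

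Every region beyond position 100 took a larger share of all reads in both mutant libraries than in both wild-type libraries. Ends at positions 101 to 200 made up 5.96% ± 0.181 of wild-type reads and 14.0% ± 4.87 of mutant reads (SD, n = 2), a ratio of 2.35. The share of ends at 201 to 300 was 1.10% ± 0.121 against 2.00% ± 0.396, and that at 301 to 400 was 1.25% ± 0.0102 against 2.53% ± 0.181. At positions 401 to 446, the last part of the 5′ETS, the share was 0.182% ± 0.0369 in wild type and 0.814% ± 0.249 in the mutant, a ratio of 4.48. Ends inside 18S made up 0.299% ± 0.0552 of wild-type reads and 1.67% ± 0.538 of mutant reads, a ratio of 5.60. With limma on the region counts scaled by library totals, the 5 regions beyond position 100 rose and the first region fell, with adjusted p from 5.36e-06 for positions 201 to 300 and 301 to 400 to 0.0483 for positions 1 to 100. The log2 change was −0.23 ± 0.105 (SE) in the first region and 2.22 ± 0.391 in 18S. No test was made of whether the changes of 2 regions differed. The calls at 1 to 100 and 101 to 200 were lost without either wild-type library, with adjusted p from 0.0872 to 0.111, and those at 201 to 300, 401 to 446 and in 18S without mutant replicate 1, with adjusted p = 0.246, 0.246 and 0.0745. Without mutant replicate 1 the difference at 101 to 200 was 4.61 percentage points, against 8.06, and with each distinct combination of end and tail counted once the difference at 201 to 300 reversed to −1.31 points. Counted that way, the shares were 18.8% against 23.0% at 101 to 200, 8.76% against 9.43% at 301 to 400, 3.81% against 5.39% at 401 to 446 and 17.5% against 24.6% in 18S, all with smaller ratios than the reads gave. Among reads without a mismatch the differences were 1.10 points at 301 to 400, 0.334 at 401 to 446 and 0.603 in 18S, against 1.28, 0.633 and 1.37. The shares were then 0.997% against 2.09% at 301 to 400, 0.108% against 0.442% at 401 to 446 and 0.125% against 0.728% in 18S. They were lower than among all reads in both genotypes, so reads that ended in these regions carried a mismatch more often than other reads. Reads that end there can be longer than those of the main cluster and so hold more bases that can mismatch. The base C329T, described below and carried mainly by mutant reads, also counted as a mismatch. The exact two-sided permutation test of each share of all reads gave p = 0.33, the smallest value that 2 against 2 libraries allow.

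Part of these rises is tied to the lower share of the main cluster, because shares of all reads sum to a fixed total. Without absolute amounts, fewer RNAs that end in the cluster and more RNAs that end elsewhere cannot be told apart. Reads that ended outside positions 51 to 58 made up 39.8% ± 2.91 of wild-type and 71.7% ± 6.46 of mutant reads (SD, n = 2), which multiplies any other share by 1.80. Among those reads, ends inside 18S made up 0.757% ± 0.194 in wild type and 2.37% ± 0.964 in the mutant, a log2 change of 1.35 ± 0.423 (SE) with limma adjusted p = 0.0475. Ends at 401 to 446 made up 0.461% ± 0.126 and 1.16% ± 0.451 of them, with adjusted p = 0.0633. The other regions did not pass either, with adjusted p = 0.0633 at 1 to 100, 0.279 at 101 to 200, 0.758 at 201 to 300 and 0.626 at 301 to 400, and the libraries of the genotypes overlapped at 201 to 300, with 2.77% ± 0.507 and 2.78% ± 0.302, and at 301 to 400, with 3.16% ± 0.256 and 3.56% ± 0.573. The 18S call was lost without wild-type replicate 1, wild-type replicate 2 or mutant replicate 2, with adjusted p = 0.379, 0.234 and 0.0695, and kept without mutant replicate 1. The difference at 101 to 200 was 4.32 points, 0.749 without mutant replicate 1 and 7.90 without mutant replicate 2, where it passed with adjusted p = 0.00295, as did that at 1 to 100 with 0.0291. Without mutant replicate 2 the differences at 401 to 446 and in 18S were 0.376 and 0.935 points, against 0.695 and 1.62. This way of counting was chosen after the data were seen.

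**Figure D1:**
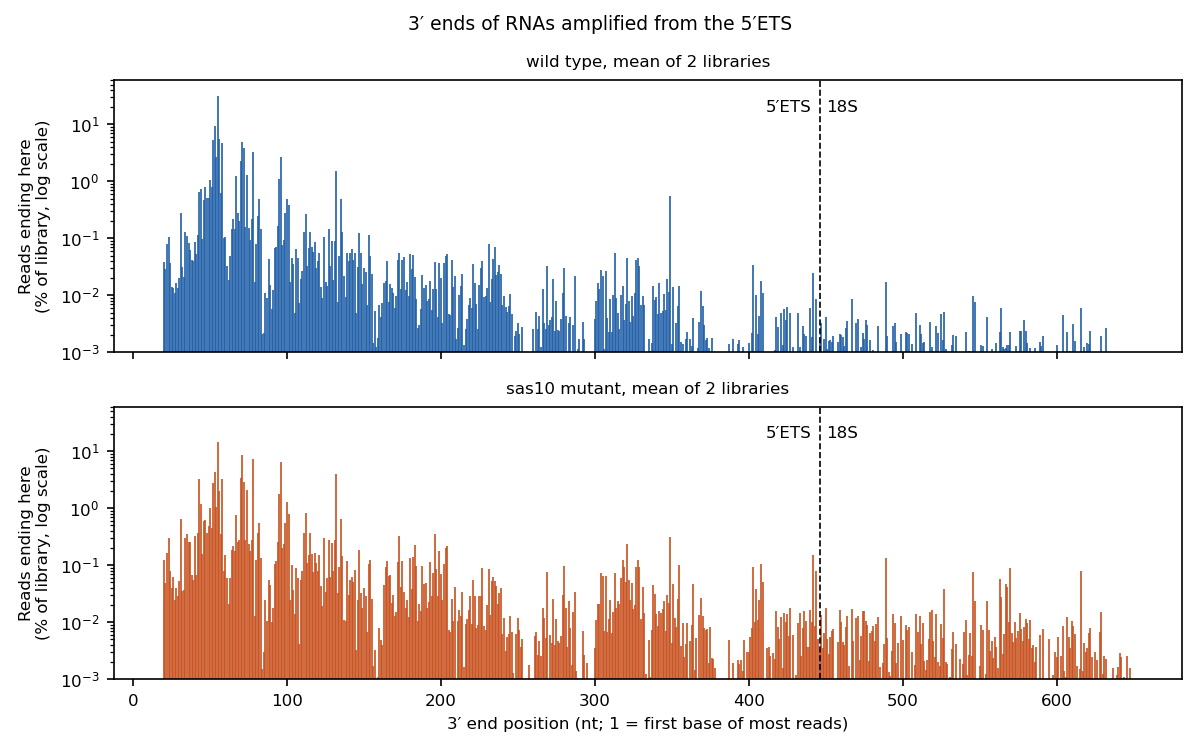
Share of reads (percent of the library, log scale) that ended at each position, in nt from the first base of most reads, as the mean of 2 wild-type libraries (top) and of 2 sas10 mutant libraries (bottom); the dashed line marks the last 5′ETS base, 446. The peak at position 55 held 31.1% of reads in wild type and 14.2% in the mutant, and ends inside 18S made up 0.299% and 1.67%.

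The wild-type profile was dominated by a cluster of ends at positions 51 to 58. This cluster held 60.2% ± 2.91 of wild-type reads and 28.3% ± 6.46 of mutant reads (SD, n = 2), 0.470 times the wild-type share. Its highest peak was position 55, 391 bases before the end of the 5′ETS, where the RNA ended in GTCCCTTCGG and the next encoded bases were ACCGTTGTGG. Ends at 55 made up 31.1% ± 1.29 of wild-type reads and 14.2% ± 3.96 of mutant reads. Relative to the typical position, ends at 55 fell by 2.49 on the log2 scale, with an SE of 0.189 and a limma adjusted p of 2.90e-12. With limma-trend the adjusted p was 0.000973. With library totals the fall was smaller, at −1.18 with limma adjusted p = 0.00235. Positions 52, 53, 54, 56 and 58 also fell under both scalings. Ends at 53 made up 9.39% ± 0.707 of wild-type and 4.31% ± 0.991 of mutant reads, and ends at 56 made up 5.50% ± 0.184 and 2.03% ± 0.348. Within the cluster, position 55 took 51.7% ± 0.349 of the ends in wild type and 49.9% ± 2.60 in the mutant, which overlapped.

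On both sides of this cluster the shares of all reads were higher in the mutant, where the lower share of the cluster by itself goes with a factor of 1.80. Ends at 19 to 50 made up 6.23% ± 0.104 of wild-type reads and 11.3% ± 0.937 of mutant reads (SD, n = 2), but 15.7% ± 0.884 and 15.9% ± 2.73 of the reads outside the cluster, which overlapped. Position 43, where the RNA ended in GCCCCTCGCC, rose from 0.644% ± 0.0418 to 3.22% ± 0.364 of reads, a log2 change of 1.02 ± 0.273 (SE) with limma adjusted p = 0.0107. Ends at 59 to 100 made up 24.8% ± 2.85 and 39.4% ± 3.10 of all reads, and 62.2% ± 2.61 and 54.96% ± 0.634 of those outside the cluster. Peaks at positions 70, 71, 78 and 96 held 2.27%, 4.89%, 3.23% and 2.67% of wild-type reads and 3.33%, 8.51%, 7.17% and 6.37% of mutant reads, and the sign of their change depended on the scaling. Relative to the typical position their log2 changes were −0.76, −0.53, −0.13 and −0.08, and with library totals they were 0.55, 0.77, 1.17 and 1.22. Position 132 held 1.49% ± 0.0687 and 3.92% ± 1.30 of reads, with a log2 change of 0.07 relative to the typical position (limma adjusted p = 0.901) and of 1.38 with library totals (adjusted p = 0.00415). Positions 50, 67 and 72 passed the threshold as lower relative to the typical position, with log2 changes of −1.45, −2.01 and −1.76, and did not pass it with library totals, where adjusted p was 0.658, 0.0711 and 0.124.

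The named positions beyond 100 that rose under both scalings were minor ends in wild type. Ends at 183, 184 and 196 made up 0.0211%, 0.00858% and 0.0379% of wild-type reads and 0.221%, 0.0983% and 0.352% of mutant reads. Position 319, 127 bases before the end of the 5′ETS, held 0.00368% ± 0.000410 of wild-type reads and 0.0926% ± 0.0111 of mutant reads (SD, n = 2), a ratio of 25.2 and a log2 change of 3.37 ± 0.546 (SE) with limma adjusted p = 2.51e-05. The neighbouring position 318 rose from 0.0144% ± 0.000535 to 0.122% ± 0.00211. The base after 318 is an encoded A, so an RNA that ended at 318 and gained an A would be counted at 319. These 2 sources of the reads at 319 cannot be told apart. The bin of 5 nt that holds both positions rose by 1.78 on the log2 scale. Positions 183 and 184 also precede an encoded A. Position 444, 2 bases before the end of the 5′ETS, rose from 0.00848% ± 0.000610 to 0.0781% ± 0.00919, a log2 change of 1.89 ± 0.496 (SE) with limma adjusted p = 0.0106. All ends at 442 to 444 together made up 0.0332% ± 0.00129 and 0.238% ± 0.0853 of reads. Ends exactly at the boundary, position 446, were rarer, at 0.00176% ± 0.000338 and 0.00330% ± 0.00144. Position 349, chosen after its values were seen, went the other way. It lies 97 bases before the end of the 5′ETS, in the sequence CACACAGCGA followed by GCGGCCGCGC, and its share fell from 0.562% ± 0.00145 to 0.316% ± 0.0852, with limma adjusted p = 9.12e-06 relative to the typical position and 0.0410 with library totals. Of the ends between 301 and 446, position 349 took 39.2% ± 1.19 in wild type and 9.36% ± 1.35 in the mutant.

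Inside 18S, recorded ends lay mainly in its first part. Amplification began at a primer in the 5′ETS, so an end further into 18S needs a longer amplified product. Whether longer products were recovered as well as shorter ones was not tested. The fall in reads along 18S therefore does not show where the precursors ended. Ends at 447 to 546, its first 100 bases, made up 0.176% ± 0.0357 of wild-type reads and 0.818% ± 0.248 of mutant reads (SD, n = 2), and ends at 547 to 646 made up 0.111% ± 0.0156 and 0.750% ± 0.207. Position 489, 43 bases into 18S, rose from 0.0175% ± 0.00472 to 0.131% ± 0.0312, and position 546, 100 bases into 18S, from 0.00985% ± 0.00541 to 0.0765% ± 0.0228. Position 570, 124 bases into 18S, rose from 0.00224% ± 0.00151 to 0.0891% ± 0.0146, a log2 change of 4.08 ± 0.675 (SE) with limma adjusted p = 3.38e-05.

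**Figure D2:**
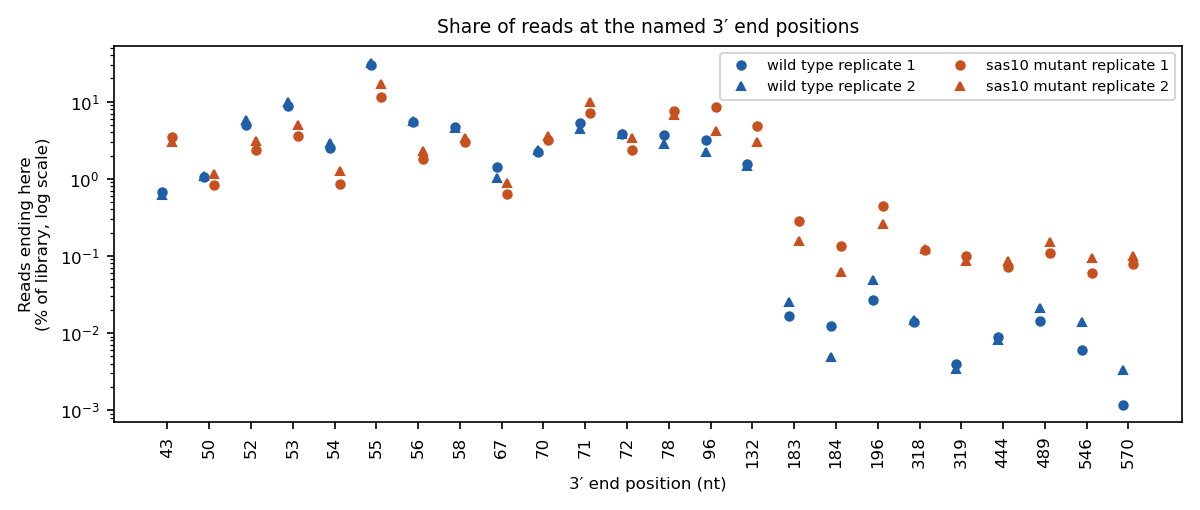
Share of reads (percent of the library, log scale) ending at each of the 24 named positions, with each point 1 library, blue for wild type and orange for the sas10 mutant, circles for replicate 1 and triangles for replicate 2. At position 55 the mutant libraries lie at 11.4% and 17.0%, below the wild-type libraries at 30.2% and 32.0%. The named positions from 183 onwards were chosen as higher in the mutant without overlap, so the separation of the libraries there follows from that choice.

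Over all positions, 609 of 884 positions with at least 1 read were tested, and these held 99.97% of reads. With TMM scaling, which sets each change against the typical position, 49 positions passed an adjusted p of 0.05 in limma, 17 higher and 32 lower in the mutant. Of the 17 higher positions 16 lay at 101 or beyond, 8 of them inside 18S, but most of the 609 tested positions lay at 101 or beyond too. Of the 32 lower positions 21 lay between 44 and 100. With library totals 184 positions passed, 175 higher and 9 lower, because the TMM factors shifted the mutant against wild type by 1.31 on the log2 scale. That shift raises the log2 change of every position, so the 17 higher positions had to keep their direction with library totals, and all 17 passed there too. This is no independent support for them. The 9 positions that were lower under both scalings were 51 to 58 and 349. Without wild-type replicate 1 the count fell to 16, and without wild-type replicate 2 to 14. The calls at 43, 50, 70, 183, 196, 318, 444, 489 and 546 were lost without either wild-type library, that at 184 without wild-type replicate 2, those at 183, 184, 196 and 546 without mutant replicate 1, and those at 489 and 546 without mutant replicate 2. In bins of 5 nt the calls at 43, 183, 184 and 196 were lost, and limma-trend lost those at 43, 70, 184 and 546, no filter those at 489 and 546, and a minimum of 100 reads that at 546.

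Reads with untemplated bases at the 3′ end were more frequent in both mutant libraries. A tail of at least 1 untemplated base was recorded on 1.58% ± 0.0110 of wild-type reads and 2.97% ± 0.700 of mutant reads (SD, n = 2). Tails made of A alone, the kind that nuclear poly(A) polymerases are known to add to RNAs bound for the exosome, were on 0.577% ± 0.0164 and 1.57% ± 0.465 of reads, a ratio of 2.71. Most of this difference went with where the RNAs ended, since at the wild-type distribution of ends, over 343 positions, the shares were 0.573% and 0.832% and 26.8% of the difference was left. The 95% Wilson intervals of the libraries, which cover counting error only, were 0.580% to 0.597% and 0.558% to 0.573% in wild type, and 1.88% to 1.91% and 1.22% to 1.26% in the mutant. Most A-only tails were 1 nt long, on 0.509% of wild-type and 1.38% of mutant reads. A-only tails of at least 3 nt were on 0.0413% ± 0.00439 and 0.112% ± 0.0117 of reads, a ratio of 2.70. T-only tails were on 0.0996% ± 0.0252 and 0.241% ± 0.110, and C-only tails on 0.194% ± 0.0110 and 0.281% ± 0.0355. G-only tails were on 0.0521% ± 0.00470 and 0.117% ± 0.0530. Tails that began with CTGA were on 0.426% ± 0.0315 and 0.358% ± 0.0727 of reads, and the libraries of the genotypes overlapped. The share of reads with any tail differed by 1.39 percentage points, by 0.895 without mutant replicate 1, and by 0.159 for tails of at least 3 nt, at 0.679% and 0.838%. With distinct combinations of end and tail counted once, a tail was on 69.2% and 69.6% of them, a difference of 0.465 points, and an A-only tail on 12.9% and 15.5%.

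A-only tails made up 36.6% ± 1.29 of all tails in wild type and 52.4% ± 3.31 in the mutant (SD, n = 2). This difference of 15.8 points was 3.72 with distinct combinations of end and tail counted once, at 18.6% and 22.4%, and 9.49 with the tails that began with CTGA left out; for tails of at least 3 nt with 1 other base allowed it was 12.7. The mean length of all tails was 2.52 ± 0.00769 nt in wild type and 2.19 ± 0.0955 nt in the mutant, and with the tails that began with CTGA left out the difference turned to 0.0384 nt longer in the mutant. It also turned when only tails of at least 3 nt, or distinct combinations of end and tail, were counted, to 0.520 and 0.232 nt. A-only tails averaged 1.28 ± 0.00892 nt and 1.31 ± 0.0384 nt, which overlapped. Among reads ending at 301 to 400, an A-only tail was on 1.26% ± 0.250 in wild type and 4.44% ± 1.29 in the mutant. Among those ending at 101 to 200 it was on 0.949% ± 0.120 and 3.02% ± 0.490, and among those ending at 401 to 446 on 1.98% ± 1.11 and 5.26% ± 2.18. The libraries of the genotypes overlapped at 201 to 300, with 2.01% ± 0.790 and 2.33% ± 0.186, and in 18S, with 1.24% ± 0.676 and 1.91% ± 0.592. An added A cannot be recorded at an end that precedes an encoded A, as at positions 55 and 318. An RNA with such an A would be counted at a later end. The exact two-sided permutation p of every tail share whose libraries did not overlap was 0.33, the smallest possible.

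**Figure D3:**
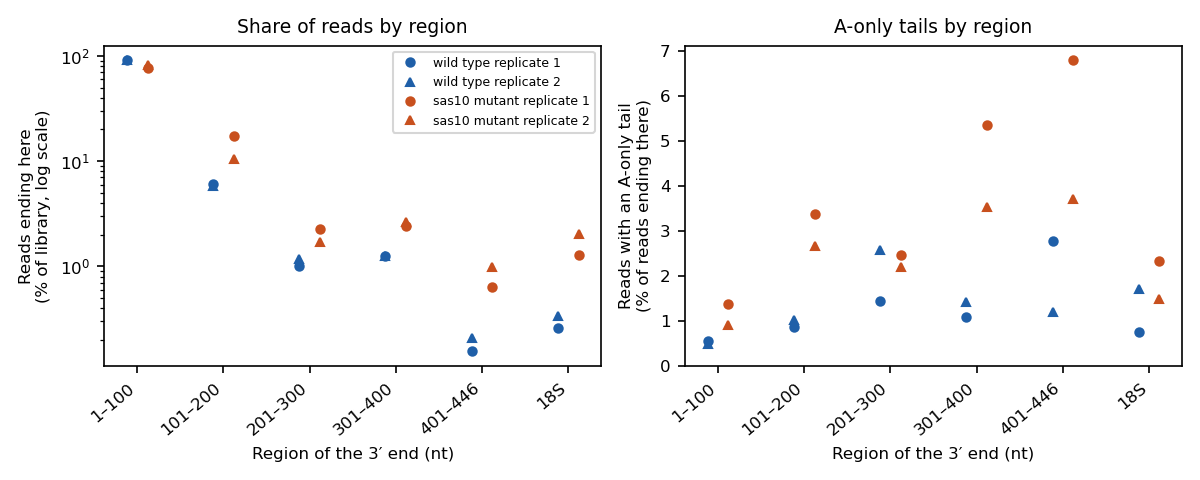
Left, share of reads (percent of the library, log scale) whose 3′ end fell in each region of the 5′ETS, in nt from the first base of most reads, or in 18S; right, share of the reads ending in each region (percent) that carried an A-only tail; each point is 1 library, blue for wild type and orange for the sas10 mutant, circles for replicate 1 and triangles for replicate 2. Wild-type and mutant libraries are apart in all 6 regions on the left, and overlap at 201 to 300 and in 18S on the right.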

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

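The tests on short inserts, adapter bases, single-base errors and sequencing error were chosen after the results were seen; the tests on depth, on rDNA copies and on the distribution of ends were not.

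A base difference outside the main measurement separated the genotypes. Among reads that cover position 329, counted from the first base of most reads, C329T was carried by 8.82% on average in the sas10 mutant. The libraries held 0.127% and 0.190% in wild type, of 32385 and 40442 covering reads, and 7.97% and 9.67% in the mutant, of 33194 and 29297. Sequencing error as the source is argued against, since the lowest mutant share was 41.84 times the highest wild-type share. A candidate explanation that stays open is that the mutant embryos carry rDNA copies that differ from those of the wild-type embryos, by descent and not by loss of Sas10, and the labels give no parents to test this. A change in which rDNA copies are used or kept in the mutant was not tested either.

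Reads ended further from the primer in the mutant. A loss of short inserts is argued against as the source of the lower share at 51 to 58. Ends at 19 to 50, the shortest, gained on those ends by 1.962 on the log2 scale (spread 0.1645, and 1.745 to 2.179 over the 4 pairs of libraries). The window was chosen after its values were seen, and the test does not bear on the ends beyond it. Among reads outside 51 to 58, ends at 19 to 50 made up 15.7% and 15.9%, which overlapped, so a bias by insert length stays open for the further ends. Lower depth of the mutant libraries was not tested by thinning, which leaves expected shares as they are (−12.28 percentage points at 1 to 100 afterwards, spread 3.042). The rDNA copies with C329T stay open too, because for reads that cover position 329, carry C there and end at 330 to 446, the log2 ratio of their share of all reads, 0.7588 (spread 0.2026; 0.8989 with all bases), is below the 0.848 that the fall of the ends at 51 to 58 alone gives, it was −0.0893, and 0.0508 with all bases, among the reads outside those ends, and reads that end before position 329 cannot show the base. Depth, other sequence differences between rDNA copies, amplification bias without molecular identifiers, a batch absent from the labels, a delay in development and the loss of Sas10 itself stay open as well, and no test bore on these.

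A larger share of mutant reads carried an A-only tail. Leftover adapter bases stay open, since the adapter sequence is not given in the sources used here; leaving out tails that begin with CTGA, a guess at such bases, cannot change the A-only share, and the share with any tail then differed by 1.458 percentage points (spread 0.4953). Single-base errors read as an added A are argued against for A-only tails of at least 3 nt alone. These were 2.705 times as frequent in the mutant (2.329 to 3.142 over the pairs of libraries). They made up 0.0704 points of the difference of 0.989 over all reads, and A-only tails of 1 nt made up 0.868. For tails of 1 nt the test cannot decide, because a single error could make them. T-only, G-only and C-only tails rose too, with ratios of 2.42, 2.25 and 1.45. With the mutant tail rates weighted by the wild-type distribution of ends, over 343 positions, the A-only share was 0.832% against 0.573%, a difference of 0.259 points (spread 0.06758) out of 0.968, so the shift of ends to tailed positions was not the whole source, although most of the difference went with it and 26.8% was left. For that remainder adapter bases, single-base errors in tails of 1 nt, stage, batch, amplification and the loss of Sas10 stay open.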

How the results depend on the processing

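Median-of-ratios scaling, limma-trend, leaving out the main cluster, the left-out CTGA tails and all alternatives for the A-only share were added after the data were seen; the others were fixed before. The planned size-factor scaling with a Wald test was not run, and median-of-ratios scaling inside limma took its place. All values are mutant minus wild type, and the cause of a change was not tested unless stated. Across the libraries left out in turn, each region and tail measure kept its direction, and the median end differed by 15 to 19 nt, against 17. A single library then stands for its genotype and is assumed to vary like the other group. Positions past the threshold numbered 14 to 57, with 2 to 26 higher and 11 to 31 lower, against 49, 17 and 32, and fewer libraries also lower the power. The calls at 319 and 570, and those at 52 to 56, 58, 67 and 72, held in each of these fits. The log2 change ranged from −0.40 to 0.12 at position 78, −0.67 to 0.46 at 96 and −0.31 to 0.43 at 132. Positions 78 and 96 turned higher without wild-type replicate 1, at 0.12 and 0.24, and 96 without mutant replicate 2, at 0.46; 132 turned lower without wild-type replicate 2, at −0.06, and without mutant replicate 1, at −0.31.

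Library totals gave 184 positions, 175 higher and 9 lower, and turned the log2 changes at 70, 71, 78 and 96 to 0.55, 0.77, 1.17 and 1.22; the cause is the 1.31 shift of the TMM factors. Bins of 5 nt gave 27, with 16 higher and 11 lower, or 59.3% higher against 34.7%, from 152 bins tested, and −0.20 for position 132. The bins of the positions 43, 183 with 184, and 196 missed the threshold, at 0.21 (adjusted p = 0.698), 0.69 (0.370) and 1.22 (0.0674), and that of 71 passed it, at −0.98. Median-of-ratios scaling gave 49, no filter 54, at least 100 reads 46 and limma-trend 36. Limma-trend lost the calls at 43, 70, 184 and 546 (adjusted p 0.0731, 0.135, 0.0663 and 0.0763), no filter those at 489 and 546 (0.0575 and 0.0697), and the minimum of 100 reads that at 546 (0.0524). Library totals lost those at 50, 67 and 72. The replicate block gave 85, with 32 higher and 53 lower. The replicate numbers were not shown to pair the libraries, since the deviations of same-numbered libraries correlated at 0.0417 over 609 positions and at 0.167 over the 252 with the most reads, across positions and with 2 pairs.

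With reads ending at 51 to 58 left out (in brackets, with each library also left out in turn), the regions differed by −7.05 percentage points (−9.43 to −4.66) at 1 to 100, 4.32 (0.749 to 7.90, the first without mutant replicate 1) at 101 to 200, 0.0120 (−0.347 to 0.371) at 201 to 300, 0.398 (−0.00656 to 0.803) at 301 to 400, 0.695 (0.376 to 1.01) at 401 to 446 and 1.62 (0.935 to 2.30) in 18S, and the median end by 11 nt; the cause is that the fall of this cluster raises every other share.

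With distinct combinations of end and tail counted once, which weights rare ends and tails (2083 to 2487 combinations per library), the difference at 201 to 300 reversed to −1.31 percentage points. It was 4.20 at 101 to 200, 0.676 at 301 to 400, 1.58 at 401 to 446 and 7.15 in 18S. The tail share then differed by 0.465, the A-only share of tails by 3.72, the A-only share of reads by 2.64, the mean tail length by 0.232 nt (reversed) and the median end by 61 nt. Reads without a mismatch gave 1.10 at 301 to 400, 0.334 at 401 to 446 and 0.603 in 18S. Tails of at least 3 nt gave 0.159 for the tail share, 0.0704 for the A-only share of reads and 0.520 nt for the mean length (reversed), and with 1 other base allowed the A-only share of tails differed by 12.7. Leaving out CTGA tails gave 9.49 for the A-only share of tails and 0.0384 nt for the mean length (reversed). Thinning, and leaving out ends at or before an encoded A, changed no direction, and with regions of 50 nt the profiles of the genotypes differed by 17.3% of reads, against 12.3%. Depth limits the minor ends, since position 570 held 0.00117% and 0.00331% of the wild-type reads.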

Other observations

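The test on base pairing was planned before its result was seen.

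Further into 18S the reads were few, and whether longer amplified products were lost was not tested. Ends at 647 to 946 made up 0.0110% ± 0.00299 of wild-type reads and 0.0988% ± 0.0772 of mutant reads (SD, n = 2). Position 616, 170 bases into 18S and chosen after its values were seen, ended in AGAGCTAATA and held 0.00603% ± 0.00113 of wild-type and 0.0773% ± 0.0148 of mutant reads, a log2 change of 2.36 ± 0.508 (SE) with limma adjusted p = 0.00162. Of the ends between 601 and 650, position 616 took 13.9% ± 0.578 in wild type and 34.7% ± 5.44 in the mutant. Position 442, 4 bases before the end of the 5′ETS, held 0.0243% ± 0.00196 and 0.152% ± 0.0739, with adjusted p = 0.109 relative to the typical position and 0.00415 with library totals.

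A-only tails were frequent at some minor ends. At position 444 they were on 29.3% of wild-type and 29.5% of mutant reads, at position 319 on 9.36% and 29.3%, and at position 570 on 6.05% and 0.337%. Reads at 319 can include RNAs that ended at 318 and gained an A, since the base after 318 is an encoded A. The wild-type rates at 319 and 570 rest on few reads. Ends at 319 made up 0.00397% and 0.00339% of the wild-type libraries, and ends at 570 made up 0.00117% and 0.00331%. Among reads with C at position 329, ends at 349 made up 56.4% and 52.3% in the wild-type libraries and 15.3% and 16.2% in the mutant libraries, so the lower share at 349 was also present without C329T.

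Other base differences were present in both genotypes. G281C was on 47.6% and 36.0% of covering reads in wild type and 38.2% and 34.4% in the mutant. The libraries of the genotypes did not overlap at C374T, on 17.9% and 5.58% in wild type and 2.67% and 4.04% in the mutant, nor at G286A, on 8.31% and 10.4% in wild type and 5.98% and 5.77% in the mutant.

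The predicted accumulation of 3′ ends at base-paired bases of the 5′ETS fold was not seen, but the test cannot decide the question. The cluster at 51 to 58 held 60.2% of wild-type reads, so the shifts mainly compared the pairing of 1 short stretch with that of other stretches. The mean over the shifts was already 0.644 in both genotypes. The share-weighted pairing probability of the last base was 0.710 in wild type and 0.670 in the mutant, and 42.99% and 41.33% of the 421 circular shifts of the end profile gave a value as high.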
